A study of Homo sapiens with 12 samples.

How the data were processed

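Polyadenylated RNA of 12 cultures was sequenced, from 3 cell lines with a control or a MYC vector in DMSO or tipifarnib for 48 h. Per the labels, libraries were made with a SMARTER mRNA-Seq kit, aligned with TopHat2 to hg19, counted with HTSeq and compared with DESeq2, with no versions or settings stated. The deposited table holds raw read counts per gene, whole numbers with 1 column per library, 57820 gene rows and 5 HTSeq summary rows. Of the gene rows 33136 had any count, and 51996 Ensembl identifiers were paired with a symbol, 42 symbols being shared by several identifiers. The annotation used for names is on another build, so it served for names and gene neighbourhood only.

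Gene counts per library were 20481363 to 26962994, and the HTSeq summary rows, which were left out, held 17.5% to 19.9% of all counts. Mitochondrial genes took 3.65% to 5.59% of gene counts. Cell line was the block, since libraries of 1 line form the pairs. After centring on each group, libraries of 1 line in other groups correlated across genes with r from 0.829 to 0.922 in 18 pairs, and libraries of other lines with r from -0.551 to -0.307 in 36 pairs. These are correlations across genes, genes are not independent replicates, and the negative values arise in part from centring on 3 libraries. The first 2 principal components held 45.5% and 38.5% of the variance.

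Genes were kept by filterByExpr over the 4 groups, leaving 17096, and scaled with TMM. Tests used the edgeR 4.0.16 quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05. Comparisons over lines used a model of line and group, with 6 residual degrees of freedom and a common biological coefficient of variation of 0.2446. Comparisons within a line, and of lines with each other, used line with each line's own MYC and tipifarnib effects, with 3 residual degrees of freedom and a coefficient of 0.1354. In that model the interaction of MYC and tipifarnib is the error term. In all 15 comparisons were made. Software was R 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

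The samples' groups, the tests, the rule for named genes and 34 gene lists were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with Benjamini-Hochberg adjustment over the lists. Members were also counted adjusted over the list alone. List members with no match in the table were BOP1, TXNIP, ACACA, UHRF1, CCL5, SOD2 and the histone genes H2AC18 and H3C2.

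Named genes were MYC, FNTA and FNTB in every comparison, and the 8 largest rises and 8 largest falls (6 and 6 in comparisons of 3 or 2 pairs) among genes that passed, had a mean log2 CPM (counts scaled to library size) of at least 1 and moved the same way in every pair. Where none passed, the 4 rises and 4 falls with the smallest p were named, and for each list described up to 4 members with the smallest p. Lists that passed camera are described for the 3 comparisons over all libraries, and only some of them for the others. Some genes the rule names, and 1 list, are not reported here. Clone names were left out, a pair at 0 counts on both sides had no direction, and for comparisons within a line the text gives the first 3 rises and falls. The mean is over all libraries, so a gene named for 1 line can have few counts there. Fitted changes over several lines depend on the prior count where libraries of a line are at 0 counts.

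In simulated counts with 2-fold and 4-fold changes, 67% and 92% of changed genes were recovered for tipifarnib over both genotypes, 65% and 94% for MYC over both treatments, and 4% and 64% for the interaction. False calls were 3.64%, 5.36% and 0% of calls there. They were 7.35% and 10.6% for tipifarnib in control and in MYC cells, 5.6% and 4.72% for MYC in DMSO and in tipifarnib, from 6.43% to 13.3% within a line, and 22.1% and 14.6% for tipifarnib and MYC effects that differ between lines. The shares above 5% exceed the nominal rate. The simulations of tipifarnib and of MYC over the lines gave no line its own effect shared by its pairs. Measured lines have such effects, so the false shares over both genotypes or both treatments do not cover that error.

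Alternatives were DESeq2 size factors, DESeq2, no low count filter, no replicate block, limma-voom, and leaving out each line in turn. An interaction model with each line's own MYC and tipifarnib effects was chosen after seeing the data; its simulated recovery was 65% and 97%, with 11% of calls false.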

Results

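Polyadenylated RNA was sequenced from 3 human cancer cell lines, the lung line A549, the ovarian line SKOV3 and the breast line MDA-MB-231. Each line carried either a control lentiviral vector or a lentiviral MYC expression vector and received either DMSO or tipifarnib, an inhibitor of the enzyme farnesyltransferase, for 48 h. Tipifarnib was given at 10 µM to A549 and at 20 µM to SKOV3 and MDA-MB-231. This gave 12 libraries in 4 groups of 3, control or MYC cells in DMSO or tipifarnib, with 1 library per cell line in each group. Gene counts per library ranged from 20481363 to 26962994, and 17096 genes were tested. Levels are counts scaled to library size (CPM). The replicates of a group were different cell lines, and the labels show no repeat culture of a line within a group, so the p-values measure only the spread between these samples. Changes are log2 fold changes ± the standard error of the fit, positive where expression was higher in tipifarnib or in MYC cells. A gene rose or fell where its Benjamini-Hochberg adjusted p in the edgeR quasi-likelihood test was under 0.05. Identifiers are given for the 3 genes followed throughout, and positions are not printed because the counts were made on another genome build than the annotation at hand.

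MYC (ENSG00000136997.10), the introduced transcription factor, was higher in MYC cells than in control cells of each line. In A549 it had 104.8 CPM in control cells with DMSO, 143.5 in control cells with tipifarnib, 911.8 in MYC cells with DMSO and 506.1 in MYC cells with tipifarnib. The same groups had 48.4, 99.7, 493.7 and 610.1 CPM in SKOV3, and 147.6, 348.9, 708.8 and 1593.1 in MDA-MB-231. The MYC to control ratio in DMSO was 8.7 in A549, 10.2 in SKOV3 and 4.8 in MDA-MB-231, and in tipifarnib it was 3.53, 6.12 and 4.57. Counts of the endogenous and the vector transcript cannot be separated.

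**Figure D1:**
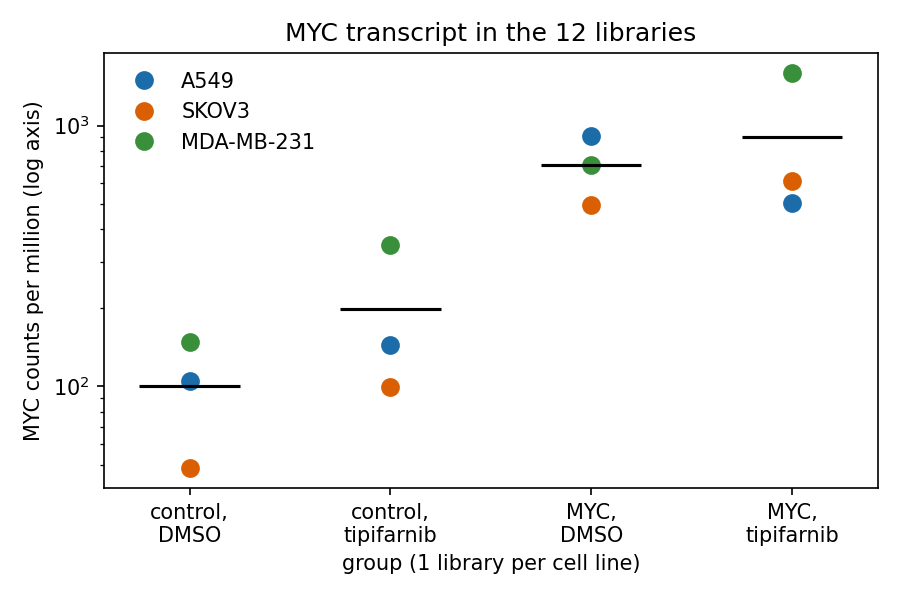
MYC CPM on a log axis in the 12 libraries, 1 point per cell line and a bar at the mean of each group. Every MYC library, from 493.7 to 1593.1, lies above every control library, from 48.4 to 348.9.

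The response to tipifarnib shared by the 3 lines was measured over both genotypes, as 6 pairs of tipifarnib and DMSO libraries. The 2 pairs of a line share that line's own response, but the model takes them as independent. Its p-values and standard errors over both genotypes can therefore be too small. Most genes of mitosis and of DNA replication fell in tipifarnib. PLK1, a mitotic kinase, changed by -1.12 ± 0.08, the proliferation marker MKI67 by -1.06 ± 0.09, the spindle motor KIF11 by -1.05 ± 0.09 and cyclin A2 (CCNA2) by -0.86 ± 0.07. PLK1 went from 206.3 to 92.6 CPM in A549 control cells, from 130.8 to 54.2 in SKOV3 and from 164.6 to 72.1 in MDA-MB-231. In the mitosis list 38 of 40 measured genes fell, and all 40 fell adjusted over the list alone. Their median was -0.80 (camera adjusted p = 2.14e-59; adjusted p = 0.0357 with an estimated correlation). Of the 40 DNA replication genes 38 fell, 39 adjusted over the list alone, with a median of -0.96 (camera adjusted p = 4.11e-46; adjusted p = 0.107 with an estimated correlation). The ribonucleotide reductase subunit RRM1 changed by -0.93 ± 0.08 and the helicase component GINS1 by -1.03 ± 0.10. The second reductase subunit RRM2 changed by -1.74 ± 0.24 and the cell cycle repressor E2F8 by -1.90 ± 0.21.

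Some inflammatory, lysosomal and immediate early genes rose in tipifarnib. The chemokine CXCL8 changed by 3.06 ± 0.36, from 1.58 to 6.23 CPM in A549 control cells, from 2.39 to 30.5 in SKOV3 and from 9.27 to 58.6 in MDA-MB-231. CXCL2 changed by 2.26 ± 0.40, the iron-binding protein LCN2 by 2.17 ± 0.38 and the NF-kB subunit RELB by 1.34 ± 0.20. Of 27 NF-kB and inflammatory genes 14 rose and none fell, 16 rose adjusted over the list alone, and the median was 1.01 (camera adjusted p = 5.19e-11; adjusted p = 0.0414 with an estimated correlation). Among 32 lysosome and autophagy genes 14 rose, 15 adjusted over the list alone, with a median of 0.33 (camera adjusted p = 3.23e-09; adjusted p = 0.0357 with an estimated correlation). The autophagy protein WIPI1 changed by 1.41 ± 0.13, the autophagy receptor SQSTM1 by 1.33 ± 0.17, the lysosomal cholesterol exporter NPC1 by 1.27 ± 0.18 and the protease cathepsin L (CTSL) by 1.00 ± 0.13. The phosphatase DUSP1 changed by 1.82 ± 0.17 and the transcription factors KLF2 and KLF6 by 2.24 ± 0.27 and 1.43 ± 0.15. In all, 10 of 27 immediate early genes rose, 13 adjusted over the list alone (median 0.65; camera adjusted p = 4.72e-09; adjusted p = 0.212 with an estimated correlation).

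Some p53 targets, stress response genes and cholesterol synthesis genes rose as well. The cyclin-dependent kinase inhibitor CDKN1A changed by 2.13 ± 0.25, the pro-apoptotic BBC3 by 1.73 ± 0.16 and PHLDA3 by 1.23 ± 0.18. CDKN1A in control cells went from 64.2 to 278.2 CPM in A549, from 5.95 to 22.9 in SKOV3 and from 33.4 to 96.4 in MDA-MB-231. In the p53 target list 7 of 25 rose, 12 adjusted over the list alone (median 0.49; camera adjusted p = 1.88e-08; adjusted p = 0.286 with an estimated correlation). Membership of this list does not show that p53 acted, since p53 activity was not measured in any line. CDKN1A changed by 2.12 in A549, 2.74 in SKOV3 and 1.52 in MDA-MB-231. The stress cytokine GDF15 changed by 2.94 ± 0.44, the mTOR inhibitor DDIT4 by 1.27 ± 0.29, the tRNA synthetase WARS1 by 0.93 ± 0.22 and HERPUD1, of endoplasmic reticulum degradation, by 0.61 ± 0.13. Of 32 integrated stress response genes 10 rose, and 20 rose and 1 fell adjusted over the list alone (median 0.79; camera adjusted p = 4.54e-11; adjusted p = 0.346 with an estimated correlation). The sterol enzymes MSMO1 and FDFT1 changed by 1.52 ± 0.20 and 0.82 ± 0.18, the sterol sensor INSIG1 by 1.22 ± 0.26 and the sterol carrier STARD4 by 0.68 ± 0.12. Cholesterol synthesis had 8 of 27 genes up, 14 adjusted over the list alone (median 0.62; camera adjusted p = 2.11e-09; adjusted p = 0.338 with an estimated correlation).

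Nucleotide synthesis, glycolysis and chaperone genes included falling members. PAICS and PFAS, enzymes of purine synthesis, changed by -0.64 ± 0.09 and -0.74 ± 0.11. In all 11 of 23 nucleotide and polyamine genes fell, 13 adjusted over the list alone (median -0.34; camera adjusted p = 2.11e-09; adjusted p = 0.304 with an estimated correlation). The glycolytic enzymes GPI and LDHA changed by -0.62 ± 0.09 and -0.73 ± 0.12. Of 20 glycolysis genes 8 fell and 1 rose, 8 down and 2 up adjusted over the list alone (median -0.22; camera adjusted p = 0.00436; adjusted p = 0.463 with an estimated correlation; camera adjusted p = 0.0554 without MDA-MB-231). The chaperones PDIA4 and HSP90B1 changed by -0.80 ± 0.10 and -0.57 ± 0.09 while DNAJB9 changed by 0.82 ± 0.14. Of 22 chaperones of the endoplasmic reticulum 6 fell and 1 rose, the same numbers adjusted over the list alone (median -0.16; camera adjusted p = 0.0344; adjusted p = 0.635 with an estimated correlation; camera adjusted p = 0.246 without A549 and 0.312 without MDA-MB-231). Interferon response genes had a median of 0.61 with 3 of 35 up, among them ISG15 (1.27 ± 0.36) and TAP1 (0.58 ± 0.16), and 0 adjusted over the list alone (camera adjusted p = 0.000355; adjusted p = 0.635 with an estimated correlation; camera adjusted p = 0.201 without MDA-MB-231). In that list the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over the members called no gene.

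Further lists that passed for tipifarnib were those of ribosome biogenesis, ribosomal proteins, NRF2 targets and apoptosis. Of 39 ribosome biogenesis genes 8 fell, 13 adjusted over the list alone, among them nucleolin (NCL, -0.49 ± 0.11) and FTSJ3 (-0.48 ± 0.11), with a median of -0.26 (camera adjusted p = 3.43e-05; adjusted p = 0.635 with an estimated correlation). Ribosomal protein genes had a median of -0.09 with 4 of 74 down, RPS26 (-0.41 ± 0.09), RPS2 (-0.36 ± 0.09), RPS9 (-0.33 ± 0.08) and RPSA (-0.30 ± 0.09), all uncertain for their pseudogenes (camera adjusted p = 0.0344; adjusted p = 0.78 with an estimated correlation; camera adjusted p = 0.244 without SKOV3 and 0.156 without MDA-MB-231). RPS9 and RPSA did not pass with no low count filter, nor RPSA with DESeq2 size factors. Adjusted over the list alone, 0 ribosomal protein genes passed the edgeR quasi-likelihood test. Of 24 NRF2 targets 4 rose, the same number adjusted over the list alone: the transporter ABCC3 (1.17 ± 0.17), ferritin heavy chain (FTH1, 1.19 ± 0.27), TXNRD1 (0.97 ± 0.26) and HMOX1 (2.40 ± 0.63), the last 3 higher in 5 of 6 pairs. Their list had a median of 0.30 (camera adjusted p = 0.00609; adjusted p = 0.635 with an estimated correlation; camera adjusted p = 0.12 without SKOV3 and 0.741 without MDA-MB-231). In the apoptosis list 4 of 29 rose and 1 fell, 6 and 1 adjusted over the list alone, among them BBC3, the death receptors TNFRSF10B (0.63 ± 0.14) and FAS (0.65 ± 0.17) and the falling BIRC5 (-1.06 ± 0.13). BIRC5 is also in the mitosis list and the others named are p53 targets. The list had a median of 0.33 (camera adjusted p = 0.0105; adjusted p = 0.192 with an estimated correlation; camera adjusted p = 0.0647 without A549).

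Genes of prenylation, the lipid modifications that include farnesylation, did not move one way. Farnesyltransferase itself is made of FNTA (ENSG00000168522.8), which had 0.30 ± 0.10, positive in 6 of 6 pairs, without passing (adjusted p = 0.0937 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and FNTB (ENSG00000257365.3), which had -0.41 ± 0.14 (adjusted p = 0.089 by the same test). With DESeq2 both passed, at adjusted p of 0.047 for FNTA and 0.0225 for FNTB, and with limma-voom FNTB passed at 0.0497, while over all alternatives the adjusted p reached 1 for both genes. In the other comparisons FNTA lay between -0.23 and 0.39 and FNTB between -0.54 and 0.11, and neither passed in any by the edgeR test. Of 28 prenylation genes 4 fell and 1 rose, 6 and 7 adjusted over the list alone (median 0.11; camera adjusted p = 0.929; adjusted p = 0.953 with an estimated correlation). The 4 that fell were farnesylated proteins of the nuclear envelope and the kinetochore, LMNB1 (-1.09 ± 0.12), LMNB2 (-0.69 ± 0.11), CENPF (-0.90 ± 0.10) and CENPE (-0.65 ± 0.09).

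Large rises with the same direction in all 6 pairs were in the keratin KRT34 (4.14 ± 0.71), the cytokine IL1A (3.73 ± 0.91), CXCL8, GDF15, the interferon-induced OASL (2.83 ± 0.67) and the lipoxygenase family member ALOXE3 (2.49 ± 0.39). IL1A had at most 0.27 CPM in A549, so its direction there rests on few counts. By the edgeR quasi-likelihood test within lines, IL1A did not pass in A549 (adjusted p = 0.953) and OASL passed only in MDA-MB-231 (adjusted p = 0.000336). Large falls were in the antisense transcript TM4SF18-AS1 (-2.33 ± 0.44), the anchoring protein AKAP5 (-1.96 ± 0.31), the growth factor receptor FGFR2 (-1.93 ± 0.41), AMBP (-1.90 ± 0.41), E2F8, RRM2 and the histone gene H2AC20 (-1.70 ± 0.31). H2AC20 shares reads with near-identical histone genes and TM4SF18-AS1 overlaps another transcript, so both are uncertain. In total 1929 of 17096 genes passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 796 higher and 1133 lower in tipifarnib. The count depended on the lines, with 978 genes without A549, 1174 without SKOV3 and 87 without MDA-MB-231, although these fits also hold fewer samples. The excess of falls did too, with 500 higher and 478 lower without A549, and with no low count filter 1052 were higher and 1012 lower. Of the 65 genes named for this comparison that passed, 52 passed without A549, 44 without SKOV3 and 14 without MDA-MB-231, among the last PLK1, CCNA2, MKI67, KIF11, CDKN1A, BBC3 and DUSP1. List calls held with an estimated correlation for mitosis, NF-kB and lysosome genes in this comparison and within MYC cells, and for mitosis and lysosome genes within control cells, and for no list in any other comparison.

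**Figure D2:**
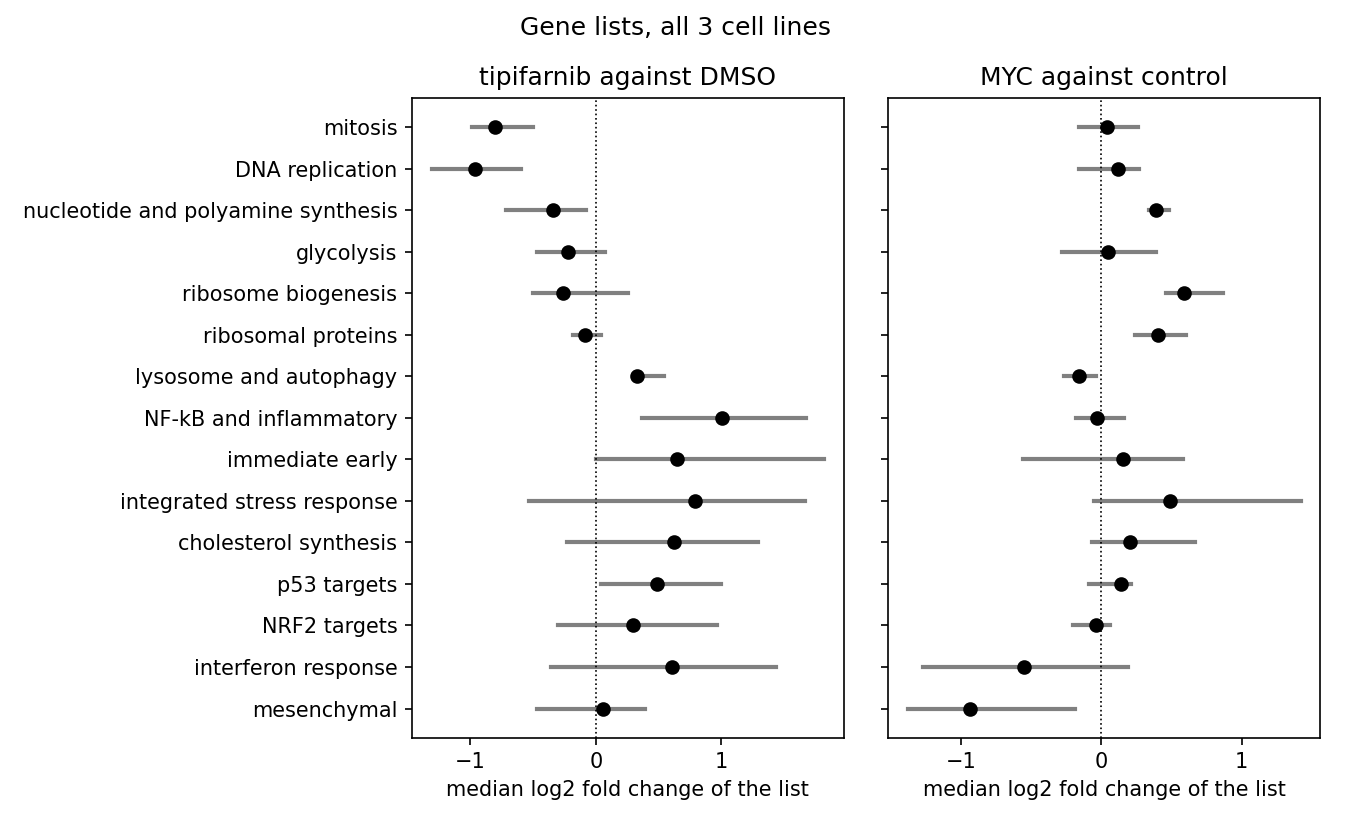
Median log2 fold change of each gene list over the 3 cell lines (points) for tipifarnib against DMSO and for MYC against control, with grey lines from the lowest to the highest median of the 6 pairs. Mitosis and DNA replication lie at -0.80 and -0.96 in tipifarnib, and ribosome biogenesis at 0.59 in MYC cells.

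The difference of MYC from control cells shared by the 3 lines was measured over both treatments, again as 6 pairs. The 2 pairs of a line were again taken as independent, so p-values and standard errors can be too small. Most genes of ribosome production rose. MYC itself changed by 2.61 ± 0.24, the nucleolar proteins LYAR and GNL3 by 1.09 ± 0.14 and 0.76 ± 0.10, and the RNA polymerase I subunits POLR1B and POLR1C by 0.75 ± 0.10 and 0.74 ± 0.11. Of 39 ribosome biogenesis genes 29 rose and none fell, 35 adjusted over the list alone, and all 39 were positive, with a median of 0.59 (camera adjusted p = 4.11e-30; adjusted p = 0.326 with an estimated correlation). Ribosomal protein genes were all positive too: 52 of 74 rose, 63 adjusted over the list alone, with a median of 0.40 (camera adjusted p = 7.17e-33; adjusted p = 0.326 with an estimated correlation). RPL18 changed by 0.53 ± 0.08, RPS24 by 0.55 ± 0.08, RPL36 by 0.58 ± 0.09 and RPS19 by 0.51 ± 0.08, although ribosomal protein genes have many pseudogenes and their counts are uncertain to that extent. The purine enzymes PPAT (0.65 ± 0.08), GART (0.69 ± 0.11), PAICS (0.53 ± 0.09) and IMPDH2 (0.54 ± 0.09) led the nucleotide and polyamine list, where 10 of 23 rose, 16 adjusted over the list alone (median 0.39; camera adjusted p = 1.44e-10; adjusted p = 0.327 with an estimated correlation).

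Some mesenchymal and interferon response genes fell in MYC cells. Fibronectin (FN1) changed by -2.77 ± 0.41, and in DMSO it went from 613.9 CPM in control cells to 39.2 in MYC cells of A549, from 3124.7 to 562.6 in SKOV3 and from 234.2 to 66.5 in MDA-MB-231. The protease MMP2 changed by -1.73 ± 0.33, the matrix protein TGFBI by -1.37 ± 0.27 and N-cadherin (CDH2) by -1.12 ± 0.22, with MMP2 lower in 5 of 6 pairs and CDH2 in 4 of 6. Of 25 mesenchymal genes 7 fell and 2 rose, 14 and 2 adjusted over the list alone (median -0.94; camera adjusted p = 1.43e-06; adjusted p = 0.326 with an estimated correlation). The list of genes typical of MDA-MB-231, which shares VIM, ZEB1 and TGFBI with the mesenchymal list, had 2 of 9 down, 6 adjusted over the list alone (median -0.80; camera adjusted p = 0.000139; adjusted p = 0.327 with an estimated correlation). The interferon signalling factor STAT2 changed by -0.69 ± 0.13, SAMD9L by -1.42 ± 0.28 and the RNA sensor RIGI by -0.82 ± 0.20. In all 6 of 35 interferon genes fell, the same number adjusted over the list alone (median -0.55; camera adjusted p = 5.23e-05; adjusted p = 0.931 with an estimated correlation). Of 32 lysosome and autophagy genes 2 fell, the protease cathepsin B (CTSB, -0.52 ± 0.11) and the proton pump subunit ATP6V0D1 (-0.40 ± 0.09), and 7 adjusted over the list alone (median -0.16; camera adjusted p = 0.0051; adjusted p = 0.326 with an estimated correlation). Integrated stress genes had a median of 0.49 with 1 of 32 up, GDF15 (1.56 ± 0.40), and 0 adjusted over the list alone by the edgeR quasi-likelihood test (camera adjusted p = 0.000331; adjusted p = 0.931 with an estimated correlation).

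The largest rises in MYC cells besides MYC were in the adhesion protein CADM2 (3.86 ± 0.86), the G protein regulator RGS16 (3.59 ± 0.54), EPB41L3 (2.20 ± 0.50), RADX (2.17 ± 0.54), the amino acid transporter SLC16A10 (2.01 ± 0.27), the ligand WNT10B (1.97 ± 0.35) and JPH1 (1.89 ± 0.42). By the edgeR quasi-likelihood test within lines, RGS16 and SLC16A10 passed in each line and EPB41L3 in none (adjusted p = 0.152 in A549, 0.2 in SKOV3 and 0.074 in MDA-MB-231). By that test CADM2, RADX and JPH1 did not pass in MDA-MB-231 (adjusted p = 0.555, 0.153 and 0.0567), nor WNT10B in SKOV3 (adjusted p = 0.113). CADM2 had at most 0.33 CPM in MDA-MB-231. After FN1 the largest falls were in CCBE1 (-2.67 ± 0.37), CCDC80 (-2.60 ± 0.55), the tight junction protein CLDN2 (-2.56 ± 0.54), ABTB3 (-2.34 ± 0.46), RNF182 (-2.21 ± 0.52), JPH2 (-2.14 ± 0.38) and MDGA1 (-2.06 ± 0.51). ABTB3 had at most 0.14 CPM in MDA-MB-231, so its direction there rests on few counts. In all 1256 genes passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 770 higher and 486 lower in MYC cells. The count was lower without any 1 line, at 10 without A549, 14 without SKOV3 and 148 without MDA-MB-231, and of the 37 genes named for this comparison that passed, 3, 1 and 9 did so in those fits. These fits also hold fewer samples. In the edgeR quasi-likelihood test they had 2361, 3663 and 3474 genes at an unadjusted p under 0.05, against 4149 with all lines. Of the genes called, 3 were higher and 7 lower without A549, 12 higher and 2 lower without SKOV3, and 59 higher and 89 lower without MDA-MB-231. Without SKOV3 MYC itself had 2.41 with an adjusted p of 0.0587 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

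The series asks which genes go with a different sensitivity to tipifarnib in MYC cells, which is the interaction of MYC and tipifarnib. A positive value here means that a gene was higher in tipifarnib relative to DMSO in MYC cells than in control cells. Mitosis genes were positive in 40 of 40 cases, with a median of 0.21 beside medians of -0.92 for tipifarnib in control cells and -0.69 in MYC cells (camera adjusted p = 1.9e-11; adjusted p = 0.578 with an estimated correlation), and the kinesin KIF2C had 0.33 ± 0.17 and securin (PTTG1) 0.30 ± 0.16. Integrated stress genes were negative in 30 of 32 cases, with a median of -0.53 (camera adjusted p = 3.55e-08; adjusted p = 0.578 with an estimated correlation; camera adjusted p = 0.464 without A549), CHAC1 having -1.89 ± 1.12 and SESN2 -1.44 ± 0.79. Chaperones of the endoplasmic reticulum were positive in 18 of 22 cases, with a median of 0.27 (camera adjusted p = 1.92e-06; adjusted p = 0.578 with an estimated correlation), HSP90B1 having 0.48 ± 0.19 and PDIA4 0.43 ± 0.19. In all 10 lists passed camera for the interaction, none with an estimated correlation, and 5 of the 10 were lost without A549, 5 without SKOV3 and 2 without MDA-MB-231. Glycolysis had a median of 0.17 (18 of 20 positive, camera adjusted p = 0.00606, adjusted p = 0.578 with an estimated correlation), lost without A549 or SKOV3 (camera adjusted p = 0.0513 and 0.0655). DNA replication had 0.14 (37 of 40 positive, camera adjusted p = 0.0144, adjusted p = 0.85 with an estimated correlation), lost in the same fits (0.899 and 0.132). Ribosome biogenesis had -0.09 (31 of 39 negative, camera adjusted p = 0.0127, adjusted p = 0.85 with an estimated correlation), lost without SKOV3 (0.555). Epithelial markers had 0.62 (12 of 17 positive, camera adjusted p = 0.00606, adjusted p = 0.578 with an estimated correlation), lost without A549 (0.195). Xenobiotic response genes had 0.30 (10 of 14 positive, camera adjusted p = 0.0442, adjusted p = 0.578 with an estimated correlation), lost without any 1 line (0.1, 0.411 and 0.153). The list typical of MDA-MB-231 had 0.39 (8 of 9 positive, camera adjusted p = 0.00606, adjusted p = 0.578 with an estimated correlation), lost without SKOV3 (0.519). Clustered histone genes had -0.31 (8 of 9 negative, camera adjusted p = 0.00748, adjusted p = 0.564 with an estimated correlation), lost without MDA-MB-231 (0.088). Within these 10 lists the number of genes called adjusted over the list alone was 0 as well, by the edgeR quasi-likelihood test.

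No single gene passed for the interaction. The edgeR quasi-likelihood test called 0 genes after Benjamini-Hochberg adjustment, with 125 genes at an unadjusted p under 0.05, fewer than the 855 that chance alone gives. The spread of this model holds each line's own tipifarnib and MYC effects, which cancel in the interaction, so the test is too cautious here. In simulated counts it recovered 4% of 2-fold changes, so 0 calls do not show that no gene differed. DESeq2 and limma-voom used the same model and also called 0, with 118 and 185 genes at that level. Genes with the smallest p in each direction were the WNT ligand WNT7B (1.28 ± 0.28), the long noncoding RNA UCA1 (3.70 ± 1.05), MAGED1 (0.53 ± 0.16), PRR15 (1.67 ± 0.55), SNHG20 (-1.16 ± 0.39), MBD6 (-0.55 ± 0.18), TENM1 (-1.75 ± 0.60) and LTO1 (-0.50 ± 0.19), each of the same sign in 3 of 3 lines. UCA1 and TENM1 had at most 0.29 CPM in A549 and MDA-MB-231. Their sign in those lines rests on few counts and on the prior count, so it is no agreement between lines. MYC had -0.73 ± 0.45. A model with each line's own MYC and tipifarnib effects, chosen after seeing the data, also called 0 genes, with 625 at an unadjusted p under 0.05 and a smallest adjusted p of 0.136 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

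Within control cells, over 3 pairs, genes higher in tipifarnib were GDF15 (3.50 ± 0.62), CXCL8 (2.90 ± 0.50), the hormone ADM2 (2.80 ± 0.54), the glucocorticoid-induced TSC22D3 (2.57 ± 0.48), the signalling adaptor TRAF1 (2.49 ± 0.52) and KLF2 (2.30 ± 0.38). Lower genes were H2AC20 (-2.25 ± 0.45), the cell cycle factors E2F2 (-1.87 ± 0.38) and E2F8 (-1.87 ± 0.30), RRM2 (-1.86 ± 0.33), the pseudogene ZBED10P (-1.79 ± 0.38, uncertain) and PDGFRL (-1.73 ± 0.30). ZBED10P had at most 0.31 CPM in A549 and 0.1 in MDA-MB-231, and TRAF1 at most 0.43 in SKOV3. Their direction there rests on few counts. Of 40 mitosis genes 35 fell, 39 adjusted over the list alone (median -0.92; camera adjusted p = 7.07e-68; adjusted p = 0.0289 with an estimated correlation). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 305 genes, 51 higher and 254 lower, against 23 without A549 (13 higher and 10 lower) and 0 without SKOV3 or without MDA-MB-231 (2683 and 1385 genes at an unadjusted p under 0.05).

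In MYC cells genes higher in tipifarnib were the secreted FGFBP1 (3.60 ± 0.63), CXCL8 (3.22 ± 0.52), ALOXE3 (3.02 ± 0.56), the phospholipase PLCH2 (2.92 ± 0.56) and xanthine dehydrogenase (XDH, 2.86 ± 0.54). Lower genes were the collagen COL8A1 (-2.81 ± 0.29), E2F8 (-1.93 ± 0.30), the kinase inhibitor CDKN2C (-1.56 ± 0.27), the origin recognition subunit ORC1 (-1.29 ± 0.23) and WDR76 (-1.24 ± 0.20). COL8A1 had at most 0.04 CPM in A549, FGFBP1 at most 0.27 in MDA-MB-231, and PLCH2 and ALOXE3 at most 0.26 and 0.4 in SKOV3. Their direction in those lines rests on few counts. Of the mitosis genes 19 fell, 38 adjusted over the list alone (median -0.69; camera adjusted p = 6.87e-45; adjusted p = 0.0335 with an estimated correlation). Here the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 191 genes, 69 higher and 122 lower, against 73 without A549 (49 higher and 24 lower) and 0 without SKOV3 or without MDA-MB-231 (2667 and 1706 genes at an unadjusted p under 0.05). With no low count filter 309 were higher and 240 lower. The MYC transcript passed this test neither over both genotypes, with 0.55 ± 0.23 (adjusted p = 0.151), nor in either genotype, with 0.92 ± 0.32 in control cells and 0.19 ± 0.32 in MYC cells. It passed with no low count filter over both genotypes and in control cells (adjusted p = 0.0456 and 0.0466), and without A549 over both genotypes (adjusted p = 0.0465), while other alternatives gave an adjusted p of up to 1.

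MYC against control cells within 1 treatment gave values of the same kind but no calls. In DMSO genes with small p were MYC (2.97 ± 0.35), TBC1D30 (2.02 ± 0.26), the membrane protein STOM (1.23 ± 0.16), TAF4B (1.79 ± 0.24), WNT7B (-1.71 ± 0.20), ZMIZ1 (-0.81 ± 0.12), the mitophagy receptor BNIP3L (-0.94 ± 0.15) and CEMIP2 (-1.05 ± 0.16). In tipifarnib they were TEX15 (4.27 ± 0.60), the mitochondrial chaperone TRAP1 (1.01 ± 0.14), MYC (2.24 ± 0.33), TBC1D30 (1.74 ± 0.26), OLFML2A (-1.45 ± 0.23), AOPEP (-0.61 ± 0.11) and SYTL2 (-1.42 ± 0.25). TEX15 had at most 0.27 CPM in SKOV3 and MDA-MB-231, so its change rests on A549. Adjusted over the list alone, 33 of 39 ribosome biogenesis genes rose in DMSO (median 0.63; camera adjusted p = 1.63e-28; adjusted p = 0.366 with an estimated correlation) and 29 rose in tipifarnib (median 0.51; camera adjusted p = 7.84e-24; adjusted p = 0.392 with an estimated correlation), against 0 over all genes tested. In DMSO the edgeR quasi-likelihood test called 0 genes, with 2667 at an unadjusted p under 0.05, where DESeq2 called 905 and limma-voom 209. In tipifarnib it called 0 genes, with 2096 at an unadjusted p under 0.05, where DESeq2 called 415 and limma-voom 34. MYC itself passed with DESeq2, no low count filter and limma-voom, at adjusted p of 6.09e-15, 6.66e-07 and 0.0186 in DMSO and 1.96e-07, 9.19e-05 and 0.044 in tipifarnib, and the other alternatives gave up to 1.

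Within A549, over 2 pairs, most p53 targets were higher in tipifarnib. BTG2 changed by 1.90 ± 0.20, TP53INP1 by 1.78 ± 0.18, ZMAT3 by 1.59 ± 0.16 and MDM2, the ubiquitin ligase of p53, by 0.94 ± 0.11. Of 25 p53 targets 19 rose and none fell, 23 adjusted over the list alone, and all 25 were positive (median 0.92; camera adjusted p = 8.08e-29; adjusted p = 0.0687 with an estimated correlation). Of 24 NRF2 targets 7 fell and 1 rose, 12 and 1 adjusted over the list alone (median -0.38; camera adjusted p = 3.64e-05; adjusted p = 0.288 with an estimated correlation). OSGIN1 changed by -1.29 ± 0.20, GCLC, of glutathione synthesis, by -0.82 ± 0.13, and the aldo-keto reductases AKR1C2 and AKR1C3 by -1.03 ± 0.17 and -0.74 ± 0.13. AKR1C genes are close copies of each other and uncertain. The largest changes included the receptor ADGRF1 (3.91 ± 0.58), WNT7A (3.54 ± 0.63) and the protease PAPPA2, with 1 count in DMSO and 25 in tipifarnib (ratio 26.6, interval 4.35 to 1090), and falls in AFP (-5.86 ± 1.27), MT1E (12 counts against 0, at least 1.22-fold lower) and HLA-DRA (21 counts against 0, with no fold given). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 1373 genes, 608 higher and 765 lower, and with no low count filter 1289 were higher and 1032 lower.

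In A549 16 of 25 mesenchymal genes were lower in MYC cells than in control cells. FN1 changed by -4.15 ± 0.15, the collagens COL5A1 and COL4A2 by -4.03 ± 0.14 and -2.27 ± 0.17, and TGFBI by -1.91 ± 0.14. In this list 4 genes rose, and 16 fell and 5 rose adjusted over the list alone (median -1.33; camera adjusted p = 2.67e-12; adjusted p = 0.269 with an estimated correlation). The list typical of MDA-MB-231 had 6 of 9 down, 7 adjusted over the list alone (camera adjusted p = 4.71e-06; adjusted p = 0.595 with an estimated correlation). The protocadherin PCDH11X had 0 counts in control cells and 86 in MYC cells, at least 10.2-fold higher, the receptor EPHA3 had 0 and 74, at least 9.56-fold higher, and ZNF804A had 0 and 67, at least 10.1-fold higher. The pseudogene AACSP1 had 19 counts in control cells and 0 in MYC cells, at least 1.98-fold lower and uncertain, and the cadherin CDH4 changed by -5.94 ± 0.20. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment 3034 genes passed, 1700 higher and 1334 lower. In simulated data between 6.43% and 13.3% of the calls within a line were false. Bounds use 3 counts per library in place of 0, and bounds and intervals cover counting error only.

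In SKOV3 most cholesterol synthesis and integrated stress genes were higher in tipifarnib. The sterol enzymes ACAT2, MSMO1 and SQLE changed by 2.06 ± 0.20, 1.90 ± 0.17 and 1.34 ± 0.14. Of 27 cholesterol synthesis genes 21 rose, 22 adjusted over the list alone (median 1.14; camera adjusted p = 2.05e-23; adjusted p = 0.254 with an estimated correlation). The serine synthesis enzyme PHGDH changed by 3.55 ± 0.41, GDF15 by 3.28 ± 0.33, WARS1 by 1.64 ± 0.18 and HERPUD1 by 1.03 ± 0.12. Of 32 integrated stress genes 26 rose, with 29 up and 1 down adjusted over the list alone (median 1.46; camera adjusted p = 5.44e-25; adjusted p = 0.254 with an estimated correlation). Of 7 measured fibroblast markers, a list that shares POSTN, COL1A1, COL1A2 and COL3A1 with the mesenchymal list, 3 fell, 6 adjusted over the list alone (camera adjusted p = 7.26e-05; adjusted p = 0.319 with an estimated correlation). KRT34 had 0 counts in DMSO and 176 in tipifarnib, at least 7.9-fold higher, and the glucose transporter SLC2A3 had 0 and 31 and TMEM255B 0 and 27, each at least 3.59-fold higher. Falls included the carotene oxygenase BCO1 (82 counts against 1, ratio 79.1, interval 13.8 to 3160), SELENBP1 (63 against 1, ratio 60.8, interval 10.5 to 2440) and KLHL4 (44 against 1, ratio 42.5, interval 7.23 to 1720). In all 2401 genes passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 1123 higher and 1278 lower, and with no low count filter 1675 were higher and 1603 lower. MYC had 0.67 ± 0.27, which passed with no low count filter (adjusted p = 2.11e-06) and not with the other alternatives (up to 0.289).

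In MYC cells of SKOV3 13 of 25 mesenchymal genes were lower and none higher, 15 and 2 adjusted over the list alone (median -0.99; camera adjusted p = 2.22e-13; adjusted p = 0.128 with an estimated correlation). FN1 changed by -2.57 ± 0.14, the matrix protein THBS1 by -2.36 ± 0.21, COL5A1 by -1.36 ± 0.12 and CDH2 by -1.22 ± 0.15. The receptor kinase ERBB2 changed by -1.22 ± 0.12 with MYC and by -1.08 ± 0.12 with tipifarnib. Its level was 5746.7 CPM in control cells with DMSO, 2834.8 with tipifarnib, 2577.8 in MYC cells with DMSO and 1168.6 with tipifarnib. CADM2 had 0 counts in control cells and 55 in MYC cells, at least 1.72-fold higher, while ACTL8 changed by 5.58 ± 0.44, the anion exchanger SLC26A7 by 5.10 ± 0.96, TENM2 by -4.06 ± 0.42 and the neurotrophic factor receptor GFRA1 by -3.92 ± 0.29. KRTAP2-3 had 20 counts in control cells and 0 in MYC cells, with no fold given. Between MYC and control cells of SKOV3 1553 genes differed by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 783 higher and 770 lower. The balance turned with DESeq2 size factors (721 and 802), DESeq2 (896 and 987) and no low count filter (1119 and 1322).

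In MDA-MB-231 most interferon response and NRF2 target genes were higher in tipifarnib. IFIT2 changed by 4.53 ± 0.22, from 14.98 to 404.04 CPM in control cells and from 7.28 to 141.0 in MYC cells, IFIT3 by 3.28 ± 0.21, the RNA sensor IFIH1 by 3.31 ± 0.21 and DDX60 by 2.93 ± 0.24. Of 35 interferon genes 23 rose and none fell, 25 and 1 adjusted over the list alone (median 1.03; camera adjusted p = 4.11e-18; adjusted p = 0.202 with an estimated correlation). Heme oxygenase HMOX1 changed by 3.59 ± 0.22, AKR1C1 by 3.37 ± 0.27, thioredoxin reductase TXNRD1 by 1.57 ± 0.12 and ferritin light chain FTL by 1.42 ± 0.12. Of 24 NRF2 targets 16 rose, with 18 up and 1 down adjusted over the list alone (median 0.89; camera adjusted p = 2.55e-14; adjusted p = 0.152 with an estimated correlation). The list typical of A549, which shares several members, AKR1C1 and AKR1C2 among them, with the NRF2 list, had 2 of 8 genes up, the same number adjusted over the list alone (camera adjusted p = 0.0155; adjusted p = 0.397 with an estimated correlation). MYC changed by 1.20 ± 0.26. STK32A had 0 counts in DMSO and 17 in tipifarnib, at least 2.01-fold higher, and KRT14 and ZFP3 had 0 and 20 and 0 and 21, with no fold given. WT1, PPP1R14A and ID4 went from 11, 10 and 7 counts to 0, again with no fold. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 3878 genes, 1811 higher and 2067 lower, and with no low count filter 2281 were higher and 2168 lower.

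In MYC cells of MDA-MB-231 11 of 35 interferon response genes were lower than in control cells. OAS2 and OAS3, antiviral synthetases, changed by -2.47 ± 0.35 and -2.05 ± 0.27 and IFIT3 by -1.32 ± 0.19. Adjusted over the list alone, 23 fell (median -1.04; camera adjusted p = 1.44e-21; adjusted p = 0.479 with an estimated correlation). COBL had 0 counts in control cells and 23 in MYC cells, at least 1.5-fold higher, AADAC changed by 3.60 ± 0.53, PODXL2 by 2.47 ± 0.27, butyrylcholinesterase (BCHE) by -3.67 ± 0.59 and the phosphodiesterase PDE7B by -3.27 ± 0.37. C1orf115 went from 11 counts to 0, with no fold given. In all 281 genes passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 139 higher and 142 lower, against 482 and 391 with DESeq2, 117 and 140 with DESeq2 size factors and 585 and 724 with no low count filter.

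**Figure D3:**
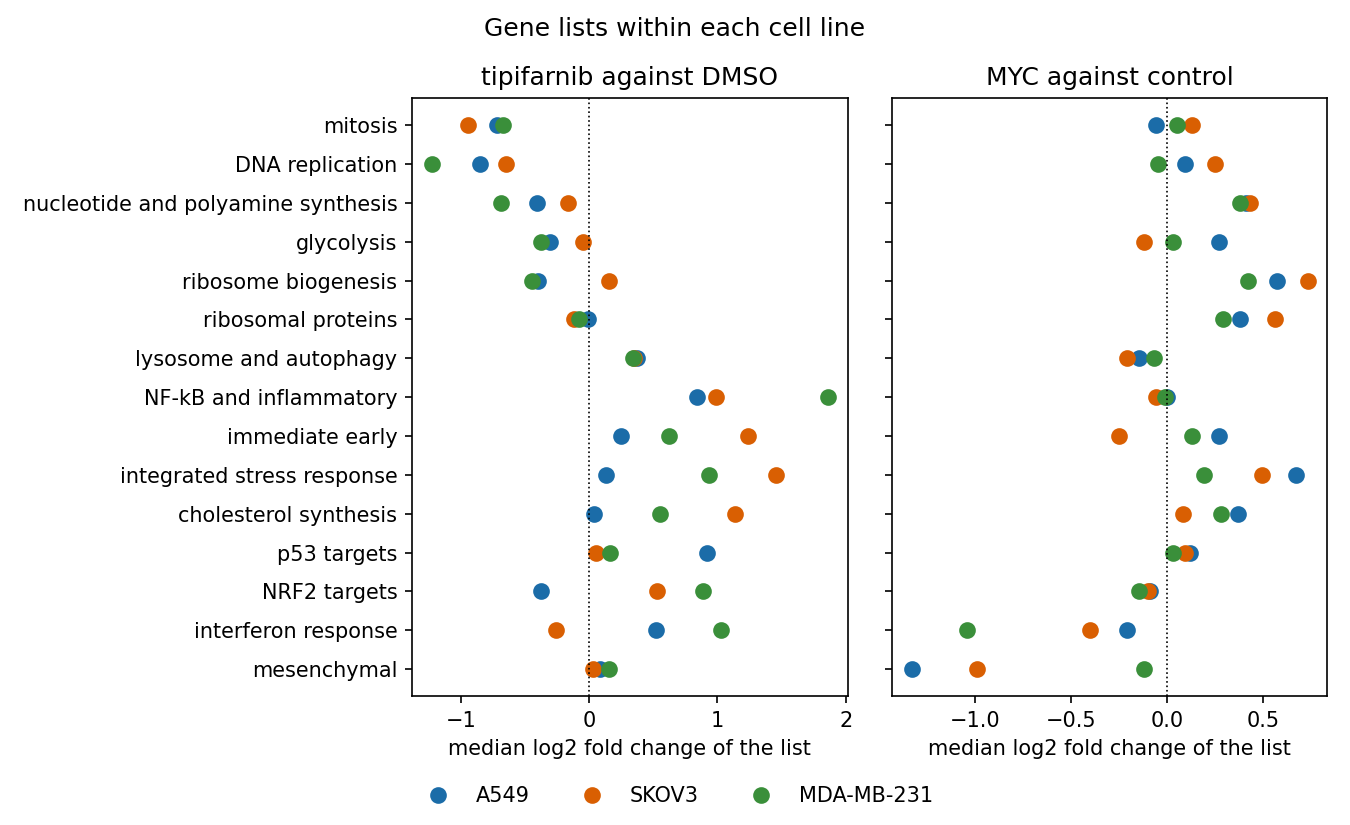
Median log2 fold change of each gene list within each cell line, for tipifarnib against DMSO and for MYC against control, 1 point per line. With tipifarnib, p53 targets lie at 0.92 in A549 and interferon genes at 1.03 in MDA-MB-231, and with MYC, mesenchymal genes lie at -1.33 in A549.

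Whether an effect differed between the lines was tested directly, with an F-test over the 3 lines. For tipifarnib 1314 genes differed by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, against 1764 between SKOV3 and MDA-MB-231 alone, 306 between A549 and MDA-MB-231 and 118 between A549 and SKOV3. For MYC 524 genes differed by the same test, against 91, 425 and 237 for those pairs. SKOV3 and MDA-MB-231 received the same 20 µM of tipifarnib, so dose does not part these lines, while line and dose cannot be told apart for A549 against either. In simulated data 22.1% and 14.6% of the calls of these tests were false. For MYC the p-values and this share do not cover other differences between a line's MYC and control cultures.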

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

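The tests of neighbouring genes, of well counted p53 targets and of other splits of the libraries were chosen after the result was seen. Leaving out a line and the estimated correlation were set before, and their use to weigh the mitosis genes was chosen after the result was seen. The results listed here stand out because an effect differed between cell lines in a test of that difference, the edgeR quasi-likelihood F-test with Benjamini-Hochberg adjustment, or camera for lists. Values in brackets after genes are adjusted p of that test.

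The effect of tipifarnib differed between lines in 1314 genes. By this test with Benjamini-Hochberg adjustment they included CXCL8 (0.0449), GDF15 (0.0177), OASL (0.0362), RRM2 (0.00706), CXCL2 (0.0268), SQSTM1 (0.0217), NPC1 (0.0097), HERPUD1 (0.049), WARS1 (0.0248), MSMO1 (0.0364) and FDFT1 (0.0473). They also included TAP1 (0.0416), E2F2 (0.0348), CDKN2C (0.0388), ADGRF1 (0.0167), WNT7A (0.0436), MT1E (0.0461), ZMAT3 (0.00924), TP53INP1 (0.00736), BTG2 (0.00116), MDM2 (0.00563), OSGIN1 (0.00295) and GCLC (0.00573). Further genes were AKR1C2 (0.00409), AKR1C3 (0.00473), SLC2A3 (0.00423), BCO1 (0.0305), SELENBP1 (0.0289), ERBB2 (0.0114), MIEN1 (0.00376), ACAT2 (0.00562), SQLE (0.0138), PHGDH (0.0179) and ZFP3 (0.0275). The last were PPP1R14A (0.0414), IFIT2 (0.00116), IFIT3 (0.00295), IFIH1 (0.00116), DDX60 (0.00423), HMOX1 (0.00116), TXNRD1 (0.00503), AKR1C1 (0.00295), FTL (0.00189), ABCC3 (0.0311) and FTH1 (0.0465). Between SKOV3 and MDA-MB-231, both at 20 µM, 1764 genes differed, so the dose given is not the source of these differences. Line and dose cannot be told apart where A549 differs from the others.

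The effect of MYC differed between lines in 524 genes. By the edgeR quasi-likelihood F-test with Benjamini-Hochberg adjustment they included RGS16 (0.0348), RADX (0.0296), FN1 (0.000731), CCDC80 (0.00371), RNF182 (0.00888), MDGA1 (0.00446), PCDH11X (0.0492), ZNF804A (0.00796), CDH4 (3.74e-05) and COL5A1 (8.13e-05). They also included COL4A2 (0.00362), ACTL8 (0.0235), TENM2 (0.0267), GFRA1 (0.0328), ERBB2 (0.00888), MIEN1 (0.00144), THBS1 (0.0342), AADAC (0.0251), PODXL2 (0.0267), BCHE (0.00394), PDE7B (0.0146) and OAS3 (0.0177). Each line had 1 MYC and 1 control library per treatment. Other differences between a line's MYC and control cultures therefore cannot be told apart from a MYC effect. The MYC to control ratio in DMSO also varied, at 8.7 in A549, 10.2 in SKOV3 and 4.8 in MDA-MB-231.

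Lists differed between lines as follows, in medians of log2 differences. With tipifarnib, p53 targets were higher in A549 than in SKOV3 by 0.53 (camera adjusted p = 2e-08; adjusted p = 0.277 with an estimated correlation) and than in MDA-MB-231 by 0.60 (camera adjusted p = 4.09e-09; adjusted p = 0.199 with an estimated correlation). Interferon genes had -1.57 in SKOV3 relative to MDA-MB-231 (camera adjusted p = 7.72e-25; adjusted p = 0.342 with an estimated correlation). Relative to SKOV3, A549 had -1.16 for cholesterol synthesis (camera adjusted p = 7.74e-20; adjusted p = 0.308 with an estimated correlation) and -1.42 for integrated stress genes (camera adjusted p = 7.74e-20; adjusted p = 0.321 with an estimated correlation). NRF2 targets in A549 had -1.24 relative to MDA-MB-231 (camera adjusted p = 3.23e-39; adjusted p = 0.108 with an estimated correlation) and -0.66 relative to SKOV3 (camera adjusted p = 2.35e-13; adjusted p = 0.277 with an estimated correlation). With MYC, mesenchymal genes had -1.22 in A549 relative to MDA-MB-231 (camera adjusted p = 6.7e-14; adjusted p = 0.267 with an estimated correlation). SKOV3 relative to MDA-MB-231 had 0.64 for interferon genes (camera adjusted p = 5.71e-06; adjusted p = 0.557 with an estimated correlation).

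In A549 3034 genes differed between MYC and control cells. RNA of another line in the A549 MYC libraries is argued against, since genes at 50 or more CPM in another line and at most 0.5 in A549 control cells reached a median of at most 0.252% of the other line's level (30 genes of SKOV3 and 11 of MDA-MB-231). Gains or losses of chromosome regions between the MYC and control cells stay open in part. Of 301 windows of 50 neighbouring genes 1.33% had a median beyond 0.3, against 0% for tipifarnib in A549, 0.997% in SKOV3 and 1.99% in MDA-MB-231, 0.332% and 0% for MYC in SKOV3 and MDA-MB-231, and 0 windows in shuffled order, and the A549 windows held 45 of the 3034 genes. Whole windows shifted beyond 0.3 are thus argued against as the source of most of the 3034 genes, while smaller regions or shifts stay open. An effect of MYC itself is a biological candidate explanation. With 1 A549 library per group, it cannot be separated from other differences between cultures.

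Of 25 targets of p53 19 rose with tipifarnib in A549, with a list median of 0.92. Scaling is argued against, since the central 95% of medians of 10000 matched random lists ended at 0.15 and 0 were as high. Too few counts in the other lines stay open. Among 24 members with a mean of at least 50 counts over all 12 libraries, the median difference from the other lines was 0.48 ± 0.24, with 20 higher in A549. This ± is a standard error over genes taken as independent, not that of the fit. The mean includes A549 and does not bound the counts in the other lines, so the test cannot decide. A549 is known to carry intact p53, which may go with the difference, but this was not tested and the dose differed as well.

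Mitosis genes had a median interaction of 0.21, with a median tipifarnib change of -0.69 in MYC cells and -0.92 in control cells. Scaling is argued against, since the central 95% of medians of matched random lists ended at 0.09. A single line as the whole source is argued against, since the median was 0.26 without A549, 0.28 without SKOV3 and 0.13 without MDA-MB-231. Chance differences between lines shared by correlated genes stay open, with an adjusted p of 0.578 by camera with an estimated correlation. An effect of MYC on the response may exist and was not tested apart from these.

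Other splits of the libraries were fitted in the same way. For tipifarnib over both genotypes 1 of 32 splits within pairs, the real one, gave as many as 1929 genes, the highest other giving 29, and for MYC over both treatments 1 of 32 gave as many as 1256, the highest other giving 3. These splits treat the 2 pairs of a line as independent, which they are not. Splits that exchange whole lines number 4, too few for a share under 0.05, and the highest others were 1 and 2. In the other comparisons too the splits were too few for a share under 0.05. There the real value and the highest other of 10 splits were 305 and 0 for tipifarnib in control cells, 191 and 4 for tipifarnib in MYC cells, 0 and 2 for MYC in DMSO and 0 and 1 for MYC in tipifarnib. A real count of 0 leaves these 10 splits, and those of the interaction, with nothing to compare. With limma on the differences within pairs, the real grouping of 15 gave 886 genes and the highest other 1 for tipifarnib effects that differ between lines, and 340 and 56 for MYC effects. For the interaction the splits used the model with each line's own effects. There the real choice of sign and the highest other of 4 both gave 0 genes by the edgeR quasi-likelihood test. For the real choice 625 genes had an unadjusted p under 0.05.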

How the results depend on the processing

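The interaction with each line's own effects was chosen after the result was seen; the other alternatives were fixed before. With DESeq2 size factors all 15 counts stayed within 1.5 times. DESeq2 called more genes for tipifarnib (2997) and MYC (2405) over all libraries, tipifarnib in control (1155) and MYC cells (1021), MYC in DMSO (905), in tipifarnib (415) and in MDA-MB-231 (873), and effects differing between lines for tipifarnib (2217) and MYC (974). With no low count filter the counts were 551 and 5.5e+02 (rounded) for tipifarnib in control and MYC cells, 402 and 99 for MYC in DMSO and in tipifarnib, 2321 for tipifarnib in A549, 2441 and 1309 for MYC in SKOV3 and MDA-MB-231, and 3198 and 1843 for tipifarnib and MYC effects differing between lines. limma-voom called 305 genes for tipifarnib in MYC cells, 209 for MYC in DMSO and 34 for MYC in tipifarnib. The cause was not tested. With no replicate block, tipifarnib and MYC over all libraries and tipifarnib in control and MYC cells each gave 0 genes, as differences between lines then enter the spread.

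Leaving out 1 line gave 87 to 1174 genes for tipifarnib and 10 to 148 for MYC over all libraries, 0 to 23 and 0 to 73 for tipifarnib in control and MYC cells, 0 to 2 for MYC in DMSO, 0 to 1 for MYC in tipifarnib, and 118 to 1764 and 91 to 425 for tipifarnib and MYC effects differing between lines. These fits hold fewer samples. Among named genes 241 kept their direction and side of the threshold with DESeq2 size factors and 1 did not, RPSA for tipifarnib, against 223 that did with DESeq2 and 223 with no filter. With limma-voom 140 did and 8 no longer passed: ISG15 and TAP1 for tipifarnib and EPB41L3, RADX, JPH1 and RNF182 for MYC over all libraries, ZBED10P in control cells and COL8A1 in MYC cells. With DESeq2 2 no longer passed, MMP2 for MYC over all libraries and SLC26A7 in SKOV3, while 124 no longer passed with no block. FNTA and FNTB for tipifarnib over both genotypes passed with DESeq2 (adjusted p = 0.047 and 0.0225), and FNTB with limma-voom (0.0497). Without A549, SKOV3 or MDA-MB-231, 61, 78 and 101 no longer passed. FNTA for MYC over both treatments turned to -0.071 without MDA-MB-231 (range -0.071 to 0.199), and MYC for tipifarnib in MYC cells turned to -0.213 (range -0.213 to 0.701). Of 35 list results 3 held with an estimated correlation, and 28 held without A549, 28 without SKOV3 and 28 without MDA-MB-231. Depth limits the genes near 0 counts in a line.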

Other observations

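The neighbour of ERBB2, MIEN1, was chosen after its values were seen. In SKOV3, where ERBB2 changed by -1.08 ± 0.12 with tipifarnib and by -1.22 ± 0.12 with MYC, MIEN1 changed by -1.15 ± 0.11 and -1.27 ± 0.11. The adjacent GRB7 had -2.54 with tipifarnib and -0.15 with MYC, STARD3 had -0.41 and -0.22, PGAP3 -0.48 and -0.50, and CDK12 -0.05 and -0.02, these also chosen after their values were seen.

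In SKOV3 the 3 fibroblast markers that fell with tipifarnib were the collagens COL1A1 (-2.05 ± 0.37), COL1A2 (-3.40 ± 0.58) and COL3A1 (-3.59 ± 0.85). The fibroblast list over all 3 lines had a camera adjusted p of 0.0748. Of the leukocyte markers 3 were measured and none passed over all 3 lines, with camera adjusted p of 0.998 for tipifarnib and 0.699 for MYC.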
